A study of Mus musculus with 31 samples.

How the data were processed

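RNA was sequenced from liver and epididymal white adipose tissue (eWAT, the visceral fat pad beside the epididymis) of male F1 mice of the C57BL/6 strain, aged 24 weeks. The samples fall into 3 arms, named LF, HF and HFLF here. Liver had 4 LF, 5 HF and 6 HFLF libraries, and eWAT had 4, 6 and 6. The arm was read from the diet tag of each sample. Per the labels' protocols, however, all animals received the same feeding, chow after weaning and then the LFD diet from 6 weeks of age for 18 weeks. The tag was therefore taken to name the arm of the paternal line, a reading that rests on the series title and that no label spells out. Libraries were made from total RNA and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Whether RNA was selected for poly(A) or depleted of rRNA, and the strand setting, are not given in the sources used here.

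Reads were aligned with STAR to GRCm38.p6, per the submitters' processing notes. The STAR version, the counting tool, the annotation release and any read filter are not given in the sources used here. The deposited tables hold whole-number counts per gene, after the authors left out genes of low CPM, per the file names. The minimum is not stated, and every gene kept reached 0.5 CPM in at least 4 libraries. These were 13677 genes in liver and 15987 in eWAT. A table of values named RPKM was also deposited by the authors for each tissue. Its values are counts scaled to library size and divided by a length, but the lengths repeat with a period of 55487 down the columns instead of following each gene. All of the 149557 liver cells and 199438 eWAT cells that could be compared repeated their length 1 period later, and the implied lengths had a correlation across genes of 0.003 in liver and 0.002 in eWAT with the genes' own exon lengths. These RPKM values were therefore not used for any level or fold change, and they entered 2 alternatives as counts of calls only. All columns were matched to samples by name. Gene symbols, coordinates, GC content and exon length came from the GENCODE M21 annotation of GRCm38, in which 13662 liver and 15969 eWAT identifiers had a symbol.

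Library totals over the deposited genes ran from 9225373 to 17268415 counts in liver and from 9278083 to 27230205 in eWAT. A count of 3 in a library, used as the floor for a gene not detected, corresponds to 0.174 to 0.325 CPM in liver and 0.110 to 0.323 in eWAT. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Samples carry separate numbers, but no label says that each number is a separate litter. The p-values of single genes therefore measure the spread between these animals. Replicates correlated at 0.963 or more on log2 CPM, the lowest pair being in eWAT LF. No pair of libraries agreed within sampling noise.

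Counts were analysed with edgeR 4.0.16 in R 4.3.3, separately for each tissue. Size factors were trimmed means of M values (TMM), and filterByExpr removed 0 genes. A quasi-likelihood model with robust estimates was fitted to all libraries of a tissue with 1 term per arm and no covariate, which left 12 residual degrees of freedom in liver and 13 in eWAT. The biological coefficient of variation was 0.194 in liver and 0.219 in eWAT. HF and HFLF were each compared with LF and with one another. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Log2 CPM values used a prior count of 2. Fold changes are log2 values with their standard errors, and CPM values are group means ± SD.

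In all, 56 lists of genes, for pathways and cell types of these tissues and of those beside them, were fixed beforehand, and lists with at least 5 genes in a table were tested, 53 in liver and 55 in eWAT. Neutrophil and mast cell markers (3 members), exocrine pancreas markers (2) and epididymis and testis genes (1) were too few in liver, as were exocrine pancreas markers in eWAT (2). Lists were tested with camera of limma 3.58.1, which asks whether the genes of a list lie higher or lower than all others, with a preset correlation of 0.01 between genes. The same test with the correlation estimated from each list (median 0.189 in liver and 0.179 in eWAT), fry, which asks whether a list's genes move on balance one way, and an exact two-sided permutation test of each list's mean log2 CPM per library were run beside it. The groups allow 126 to 924 labellings. After adjustment over all lists, 1 list at small p alone could therefore not pass the exact test, but several together could. Its adjusted result is given with this limit, and its p-values for named lists are given unadjusted. List scores are means of log2 CPM over the members.

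Differences between the tissues were tested with the same edgeR test, as the interaction of tissue and arm, in 1 fit of all 31 libraries over the 12733 genes of both tables. An alternative in limma voom took libraries of the same arm and number as the same animal (14 animals with both tissues), a pairing no label states, as a replicate block. The consensus correlation of such libraries was 0.006. Fold changes of HF and HFLF share the LF libraries. Their correlation was therefore set beside 50 simulations with no change and beside 100 labellings of the libraries, the real one included.

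The genes named were chosen by a rule. Since fewer than 5 genes passed, it took the 5 genes of smallest p in each direction against LF (mean of at least 1 CPM in one group, leaving out predicted genes and immunoglobulin or T cell receptor genes), 3 in each direction between HFLF and HF, and 3 members of each list called against LF. A fixed set of metabolic genes was always included, as were the 5 genes of smallest p in each comparison of tissues. Some genes the rule took are not reported here. The groups, tests, lists and this rule were chosen before the data were examined, as were the alternatives, except the 4 given as added later. The alternatives were a looser threshold, a minimum fold, other size factors, a stricter filter, a replicate block, 1 surrogate variable (sva 3.50.0), fits of 2 arms alone, DESeq2 1.42.0, voom with and without sample weights, the values named RPKM, estimated correlations, fry, a split of the LF libraries and leaving out each library. Those added later were leaving out the libraries high in B cell genes or in epididymis and testis genes, the exact test of list means, and leaving out libraries for the correlations.

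The edgeR and list tests were tested on simulated data with 200 genes changed, 50 at each known fold. In the liver HF comparison, for example, edgeR recovered 36% of genes changed by 1.5 and 92% of those changed by 4, and in the eWAT HFLF comparison with LF 30% and 86%. DESeq2 made more false calls there than edgeR, with 33 of 187 calls, 23 of 175 and 23 of 190 in liver (HF against LF, HFLF against LF, HFLF against HF) and 17 of 168, 18 of 164 and 30 of 180 in eWAT, against 5 to 12 for edgeR, so its calls carry that limit. In simulated data in which the TCA cycle list was moved, camera found it in all 6 comparisons and called 0 other lists. Genes were simulated without correlation between them, so the 0 says nothing on lists whose genes vary together. With an estimated correlation the moved list was found in 5 and missed in liver HF against LF (adjusted p = 0.140). Real lists had median correlations of 0.189 in liver and 0.179 in eWAT, and how often the test finds a moved list at these was not assessed. A list that did not hold may therefore still have changed, in any of the 6 comparisons. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Near-identical copies such as Gstp1 and Gstp-ps, the Mup, Cyp2c, haemoglobin and histone families and MHC class II genes may share reads, so their values are uncertain.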

Results

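RNA was sequenced from liver and epididymal white adipose tissue (eWAT) of male F1 C57BL/6 mice aged 24 weeks, in 3 arms that the labels tag LFD, HFD and HFLFD and that are named LF, HF and HFLF here. All animals were themselves fed the LFD diet for 18 weeks, per the labels, so the tag was taken to name the arm of the paternal line. Liver had 15 libraries (4 LF, 5 HF and 6 HFLF) of 9225373 to 17268415 counts, over 13677 genes. eWAT had 16 (4, 6 and 6) of 9278083 to 27230205 counts, over 15987 genes. Changes are log2 fold changes ± SE, and levels are mean CPM, counts scaled to library size, ± SD. The p-values of single genes and of the exact permutation test measure the spread between these animals. Camera p-values with the preset correlation rest largely on the spread between genes, and so do not measure the spread between animals.

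In liver, camera with its preset correlation placed genes that burn fat and detoxify higher in HF (n = 5) than in LF (n = 4), but 0 lists held with an estimated correlation (smallest adjusted p = 0.587). Cpt1a, which admits fatty acids to mitochondria, differed by 0.29 ± 0.13. Lpgat1, a phospholipid acyltransferase, differed by 0.42 ± 0.10, Pcx, which feeds the TCA cycle with oxaloacetate, by 0.38 ± 0.10, the guidance receptor Nrp2 by 0.60 ± 0.15 and the dendritic cell gene Wdfy4 by 0.82 ± 0.21. Lower in HF were the glutathione transferase Gstp1, at 866 ± 144 against 1569 ± 232 CPM (-0.86 ± 0.19), its near copy Gstp-ps (-1.02 ± 0.19), the endocytic receptor Lrp2 (-1.69 ± 0.40) and the reductase Cyb5r1 (-0.51 ± 0.13). None of these genes passed the edgeR test over all genes, in which Gstp-ps had the smallest adjusted p (0.718) and the others 1.00.

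Genes controlled by PPAR-alpha, the receptor that switches on fat use in fasting, were higher in HF as a list (27 of 28 higher, median 0.29, camera adjusted p = 9.53e-10; adjusted p = 0.587 with an estimated correlation). Their median was 0.44 without LF 2 and 0.17 without LF 3. Mitochondrial fatty acid oxidation genes were higher in all 21 members (median 0.18, adjusted p = 1.73e-07; adjusted p = 0.587 with an estimated correlation), with a median of 0.11 without LF 3. TCA cycle genes, which oxidise acetyl groups, had a mean log2 CPM of 7.16 ± 0.04 in HF and 7.04 ± 0.05 in LF (17 of 19 higher, adjusted p = 0.000227; adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, Pcx rose in the TCA cycle list, against 0 genes of any list over all genes.

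Xenobiotic metabolism genes, which make foreign compounds soluble, were higher in 29 of 42 members (median 0.22, adjusted p = 5.1e-05; adjusted p = 0.587 with an estimated correlation). The median was 0.13 without LF 1, 0.13 without LF 3 and 0.14 without HF 3. Ugt1a1, which conjugates bilirubin (0.55 ± 0.16), and Cyp2c54, a cytochrome P450 (1.02 ± 0.29), were among 4 members that rose when adjusted over the list alone (0 over all genes). Genes biased to female liver, a readout of growth hormone rhythm, were higher in 12 of 14 members (median 0.63, adjusted p = 5.15e-06, and 0.587 with an estimated correlation). Their median was 1.35 without LF 6 and 0.29 without HF 6. Only 14 of the 30 listed genes were measured, and Cyp4a10, Cyp4a14 and Acot3 of these are also on the PPAR-alpha list. Branched-chain amino acid catabolism was higher in 20 of 22 members (median 0.10, adjusted p = 0.00177; adjusted p = 0.587 with an estimated correlation), and its median was 0.05 without HF 3. Ribosomal protein genes, which build the translation machinery, were lower in 73 of 76 members (median -0.09, adjusted p = 5.15e-06; adjusted p = 0.732 with an estimated correlation), a call that ended without LF 1 (adjusted p = 0.149, median -0.04) or LF 3 (0.393, -0.02), while the median was -0.15 without LF 2 and -0.14 without LF 6.

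Single genes did not separate HF from LF liver. The edgeR test passed 0 of 13677 genes, while DESeq2 passed 1 (Gstp-ps) and limma voom 0. By edgeR 492 genes had an unadjusted p under 0.05 (262 higher and 230 lower), where 684 would be expected in each liver comparison with no change. Camera called 16 of 53 lists, 12 higher and 4 lower, and 0 of them held with an estimated correlation or with fry. The lipid synthesis genes Fasn (0.38 ± 0.51) and Scd1 (0.06 ± 0.52), their regulator Srebf1 (-0.07 ± 0.29) and the glucose-producing enzymes Pck1 (-0.04 ± 0.32) and G6pc (0.39 ± 0.52) differed by less than their standard errors.

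**Figure D1:**
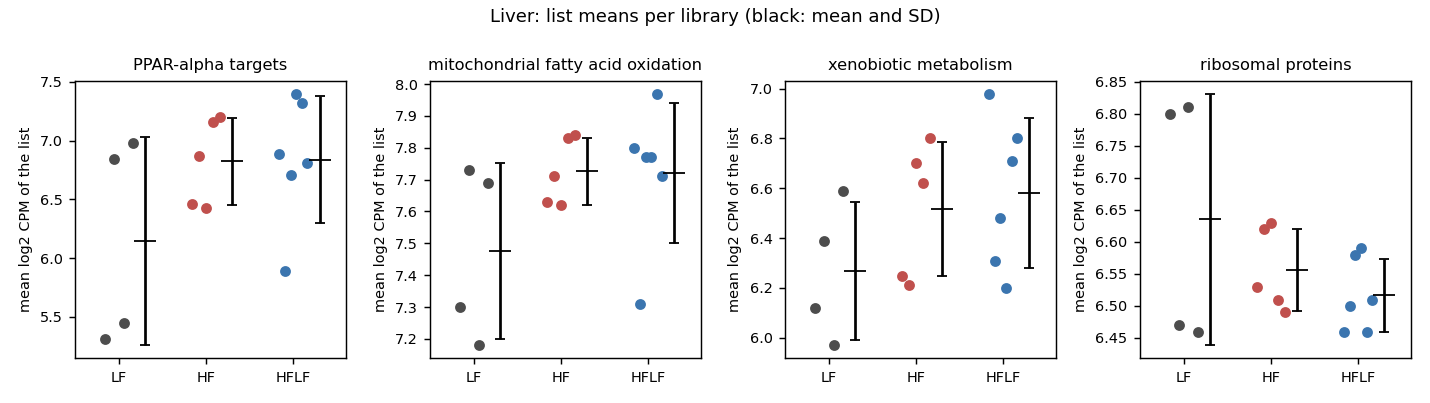
Mean log2 CPM of 4 gene lists in each liver library, with group means and SD. PPAR-alpha targets averaged 6.15 ± 0.89 in LF, 6.82 ± 0.37 in HF and 6.84 ± 0.54 in HFLF.

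In liver of the HFLF arm (n = 6), camera placed genes of fat use and detoxification higher than in LF (n = 4) and ribosomal protein genes lower, but 0 lists held with an estimated correlation (smallest adjusted p = 0.382). Nrp2 stood at 19.9 ± 3.01 CPM against 11.8 ± 2.50 (0.76 ± 0.14, adjusted p = 0.443), and A1cf, a partner in apolipoprotein B RNA editing, at 54.7 ± 10.6 against 29.1 ± 2.81 (0.91 ± 0.20). Lpgat1 (0.43 ± 0.09), the acyl-CoA synthetase Acsm3 (0.46 ± 0.10), the cytochrome P450 Cyp2c50 (0.85 ± 0.18) and the fat-use receptor Ppara (0.77 ± 0.20) also had higher means. Lower in HFLF were Arpc1b, a subunit that branches actin filaments (-0.41 ± 0.08, adjusted p = 0.443), Reep5, which shapes the endoplasmic reticulum (-0.57 ± 0.12), smooth muscle actin Acta2 (-1.02 ± 0.21), the transcription factor Foxp4 (-0.44 ± 0.10), Gstp-ps (-0.79 ± 0.18) and the stress gene Nupr1 (-1.47 ± 0.40, and -0.75 without LF 2). No gene passed over all genes.

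Ribosomal protein genes were lower in 75 of 76 members (median -0.12, camera adjusted p = 6.57e-10; adjusted p = 0.582 with an estimated correlation), with medians of -0.07 without LF 1 and -0.05 without LF 3. PPAR-alpha targets were higher in 27 of 28 members (median 0.35, adjusted p = 1.27e-08; adjusted p = 0.486 with an estimated correlation). Fatty acid oxidation genes were higher in all 21 (median 0.24, adjusted p = 5.66e-07; adjusted p = 0.486 with an estimated correlation), and the median was 0.15 without LF 3. Xenobiotic metabolism was higher in 33 of 42 members (median 0.31, adjusted p = 4.25e-07; adjusted p = 0.486 with an estimated correlation). Of these, 7 rose and 1 fell when adjusted over the list alone (0 over all genes), Cyp2c54 (1.24 ± 0.28) among them.

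Branched-chain amino acid catabolism was higher in 20 of 22 members (median 0.15, adjusted p = 3.02e-06; adjusted p = 0.382 with an estimated correlation) and kept its call without any 1 library. Female-biased liver genes, which share Cyp4a10, Cyp4a14 and Acot3 with the PPAR-alpha list, were higher in 12 of 14 (median 0.84, adjusted p = 2.19e-06, and 0.382 with an estimated correlation). Their median was 0.54 without LF 1 and 1.48 without LF 6. Genes of mitochondrial fusion, fission and biogenesis were higher in 21 of 30 members (median 0.08, adjusted p = 0.00662; adjusted p = 0.486 with an estimated correlation), a call that ended without HFLF 1 (adjusted p = 0.0545). The bile acid enzyme Cyp7a1 (0.95 ± 0.79, and 0.28 without HFLF 6) and the fasting hormone Fgf21 (0.51 ± 0.99, and -0.92 without HFLF 4) each rested on 1 library.

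Over all genes, edgeR passed 0 of 13677, with 748 at an unadjusted p under 0.05 (386 higher and 362 lower), where 684 would be expected with no change. DESeq2 passed 11, 7 higher and 4 lower, among them Nrp2, A1cf, Lpgat1 and Arpc1b, and limma voom passed 0. Camera called 19 of 53 lists, 11 higher and 8 lower, and 0 of them held with an estimated correlation or with fry. The count of lists was 7 without HFLF 1 and 12 without HFLF 5.

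No single gene passed between the HFLF (n = 6) and HF (n = 5) livers. Serpine2, an inhibitor of proteases around cells, stood at 24.8 ± 5.26 CPM in HFLF and 37.0 ± 2.50 in HF (-0.58 ± 0.13), and the chromatin protein Hmgb3 (-0.32 ± 0.10) and the membrane protein Pqlc3 (-0.93 ± 0.24) also had lower means. The stress granule protein G3bp2 (0.23 ± 0.06) and the zinc finger gene Zfp746 (0.34 ± 0.10) had higher means, all at an adjusted p of 1.00. The testis gene Fmr1nb stood at 2.17 ± 2.01 CPM in HFLF and lay under the floor of 3 counts in 4 of 5 HF libraries. Red blood cell genes, which make haemoglobin, were higher in all 9 members (median 0.47, camera adjusted p = 1.31e-05; adjusted p = 0.288 with an estimated correlation), with a mean log2 CPM of 3.52 ± 0.11 in HFLF and 3.13 ± 0.34 in HF. MHC class II genes, which present antigen, were lower in all 9 (median -0.35, adjusted p = 0.00018; adjusted p = 0.590 with an estimated correlation), and H2-Aa, H2-Eb1 and Cd74 fell when adjusted over the list alone (0 over all genes). Both calls held without any 1 library.

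Acute phase genes, secreted by liver in inflammation, were lower in 26 of 31 members (median -0.24, adjusted p = 0.000267; adjusted p = 0.760 with an estimated correlation). That call ended without HF 2 (adjusted p = 0.107, median -0.04), and the median was -0.14 without HF 1, -0.44 without HFLF 2, -0.14 without HFLF 5 and -0.12 without HFLF 6. PPAR-alpha targets (median 0.06, adjusted p = 0.990) and fatty acid oxidation genes (0.01, 0.986) did not pass. Over all genes edgeR passed 0 of 13677, and DESeq2 and limma voom passed 0 each. By edgeR 255 genes had an unadjusted p under 0.05 (130 higher and 125 lower), fewer than the 684 expected with no change. Camera called 16 of 53 lists (3 higher, 13 lower), of which 0 held with an estimated correlation or fry. The number was 10 without HF 1, HF 2 or HF 3 and 8 without HFLF 5.

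In eWAT, camera placed genes that make fat and use glucose lower in HF (n = 6) than in LF (n = 4), but 0 lists held with an estimated correlation (smallest adjusted p = 0.507). The glycolysis call ended without 4 libraries high in testis genes. Gapdh, the glycolytic dehydrogenase, stood at 322 ± 19.5 CPM against 462 ± 82.5 (-0.52 ± 0.11), and Dgat1, which completes triglycerides, at 246 ± 30.8 against 388 ± 93.5 (-0.66 ± 0.16). The dicarboxylate carrier Slc25a10 (-0.74 ± 0.18), the acyltransferase Agpat2 (-0.68 ± 0.18), the parathyroid hormone receptor Pth1r (-0.60 ± 0.14) and the fatty acid synthase Fasn (-0.93 ± 0.38, and -0.56 without LF 3) also had lower means. Higher means were seen for the histone Hist3h2a (0.50 ± 0.12), the secreted protein Fibin (0.88 ± 0.24) and the endocytic adaptor Ston1 (0.61 ± 0.16). The edgeR adjusted p was 0.689 for the smallest. The adipokines Lep (0.29 ± 0.41) and Adipoq (-0.18 ± 0.16) and the fat cell regulator Pparg (-0.08 ± 0.13) differed by less than 2 standard errors.

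Genes of OXPHOS complexes II to V, which make ATP, were lower in all 40 members (median -0.21, camera adjusted p = 9.63e-15; adjusted p = 0.507 with an estimated correlation), with a mean log2 CPM of 6.96 ± 0.10 in HF and 7.17 ± 0.20 in LF. Complex I genes were lower in all 36 (median -0.18, adjusted p = 4.48e-10; adjusted p = 0.507 with an estimated correlation). Cox5a (-0.41 ± 0.12, and -0.23 without LF 3) and Ndufs8 (-0.36 ± 0.12, and -0.24 without LF 6) were examples. LF 3, LF 6, HF 2 and HF 6, called epididymis-high here, had high levels of the epididymis and testis list (list means 2.15, 1.56, 3.74 and 4.37, against -2.80 to -0.15 in the others). Its 5 measured members were the testis genes Prm1, Prm2, Tnp1, Tnp2 and Ldhc, and no epididymis gene of the list was measured in eWAT. Without these 4 libraries both OXPHOS calls ended (adjusted p = 0.730, medians -0.01 and 0). LF 2 and LF 5 were then the only LF libraries, here and in every such test against LF. Both calls held when any 1 library was left out. Whether testis tissue or the loss of LF libraries ended them was therefore not settled. TCA cycle genes (18 of 19 lower, median -0.23, adjusted p = 4.58e-06; adjusted p = 0.523 with an estimated correlation) ended likewise (0.922), and their median was -0.09 without LF 3.

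Lipogenesis genes were lower in 26 of 28 members (median -0.34, adjusted p = 1.05e-06; adjusted p = 0.507 with an estimated correlation), with 4 that fell when adjusted over the list alone (0 over all genes), Dgat1 and Agpat2 among them. The call held without the 4 epididymis-high libraries (adjusted p = 0.0111, median -0.25), and the median was -0.22 without LF 3. Cholesterol synthesis genes were lower in 21 of 24 (median -0.22, adjusted p = 1.76e-06; adjusted p = 0.507 with an estimated correlation), led by Fdps (-0.71 ± 0.18), with medians of -0.13 without LF 2 and -0.14 without LF 2, HF 3 and HF 5. Glycolysis genes were lower in 18 of 24 (median -0.20, adjusted p = 2.46e-05; adjusted p = 0.507 with an estimated correlation), and 4 fell when adjusted over the list alone, Gapdh among them, but the call ended without the epididymis-high libraries (0.408) and the median was -0.12 without LF 6.

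Cell cycle genes were lower in 36 of 37 members (median -0.44, adjusted p = 8.25e-11; adjusted p = 0.507 with an estimated correlation), with a median of -0.14 without LF 3 and a call that ended without the epididymis-high libraries (0.549). T and NK cell genes were lower in all 33 (median -0.77, adjusted p = 2.96e-06, and 0.63 with an estimated correlation), a call that ended without LF 2 (0.411, median -0.07). It passed without LF 2, HF 3 and HF 5 together (5.83e-06, median -0.69). HF 3 and HF 5 were picked for high B cell genes, and their T cell gene Cd4 was high too (5.79 and 6.13 CPM, other HF 1.09 to 2.10). Leaving them out lowers HF, so that pass does not show lower T cell genes in HF. Glucocorticoid targets, such as the metallothionein Mt2 (1.21 ± 0.37), were higher in 17 of 22 (median 0.34, adjusted p = 0.00163; adjusted p = 0.507 with an estimated correlation), but not without LF 2 (0.0721, median 0.21) or the B-cell-high libraries (0.170), and the median was 0.22 without HF 6. Mesothelium genes, of the membrane covering the fat pad, were higher in all 19 (median 0.93, adjusted p = 0.00208; adjusted p = 0.71 with an estimated correlation), a call that ended without LF 2, HF 3 and HF 5, the libraries with high B cell genes (0.371, median 0.39). B cell genes themselves were lower in all 20 (median -0.97, adjusted p = 0.256) and did not pass, with list means of 6.31, 4.21 and 5.12 in LF 2, HF 3 and HF 5 against 0.89 to 2.62 elsewhere.

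For single genes edgeR passed 0 of 15987, with 1126 at an unadjusted p under 0.05 (451 higher and 675 lower). With no change, 799 would be expected at that p in each eWAT comparison. DESeq2 passed 12, 1 higher and 11 lower, Gapdh, Dgat1 and Agpat2 among them, and limma voom passed 0. Camera called 19 of 55 lists (5 higher, 14 lower), and 0 held with an estimated correlation or fry. The number of lists was 7 without the epididymis-high libraries.

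In HFLF eWAT (n = 6), camera placed genes for dividing cells and several immune cell lists lower than in LF (n = 4), but 0 lists held with an estimated correlation (smallest adjusted p = 0.429), and the B and T cell calls ended without LF 2. Mcm5, a subunit of the replicative helicase, stood at 6.42 ± 1.34 CPM against 14.3 ± 4.18 (-1.14 ± 0.19, adjusted p = 0.180), and Tk1, which salvages thymidine for DNA, at 3.81 ± 0.665 against 9.44 ± 3.06 (-1.30 ± 0.22, adjusted p = 0.180). Mcm6 (-0.63 ± 0.12), the licensing factor Cdt1 (-1.23 ± 0.23) and the replication clamp partner Pclaf (-1.48 ± 0.29) had lower means too. The macrophage receptor Marco (-2.38 ± 0.52), the monocyte marker Ly6c2 (-1.75 ± 0.42), the matrix protein Spp1 (-4.47 ± 1.10) and the B cell receptor partner Cd22 (-3.19 ± 0.88) also had lower means. Single LF libraries carried much of these differences: without LF 2 Ly6c2 differed by -1.0 and Cd22 by -1.12, and without LF 3 Spp1 differed by -1.78. Marco rested on LF 2 (26.3 CPM) and LF 3 (17.4), since it stood at 2.23 in LF 5, 3.85 in LF 6 and 1.57 to 2.79 in HFLF. Higher means of small size were those of the junction protein Pkp2 (0.67 ± 0.15), the catenin relative Ctnnal1 (0.52 ± 0.11), the mitochondrial lyase Clybl (0.38 ± 0.09), the actin methyltransferase Setd3 (0.26 ± 0.06) and the kinase Map3k20 (0.34 ± 0.08). No gene passed over all genes.

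As a list, cell cycle genes were lower in all 37 members (median -0.91, camera adjusted p = 3.45e-28; adjusted p = 0.429 with an estimated correlation), with a mean log2 CPM of 1.90 ± 0.29 in HFLF and 2.68 ± 0.52 in LF. Adjusted over the list alone, 30 members fell (0 over all genes). The call held without the B-cell-high libraries (median -0.97) and without the epididymis-high ones (median -0.43), and the median was -0.55 without LF 3. Macrophage genes were lower in 31 of 35 (median -0.73, adjusted p = 4.05e-11; adjusted p = 0.429 with an estimated correlation), and 13 fell when adjusted over the list alone. That median was -0.40 without LF 3 and -0.33 without the epididymis-high libraries.

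Interferon-induced genes, which answer viral signals, were lower in 32 of 38 members (median -0.27, adjusted p = 4.75e-07; adjusted p = 0.557 with an estimated correlation), Oas1a (-0.89 ± 0.24) and Irgm1 (-0.41 ± 0.11) among them. B cell and plasma cell genes were lower in all 20 (median -3.14, adjusted p = 3.47e-07; adjusted p = 0.557 with an estimated correlation), and 18 fell when adjusted over the list alone. The call ended without LF 2 (adjusted p = 0.0961, median -0.49), the library with the highest level of these genes. It passed without LF 2, HF 3 and HF 5 together (0.00601, median -0.49). HF 3 and HF 5 are not in this comparison and enter only the estimate of spread. That pass therefore compares the same libraries as without LF 2 and does not show that the call holds without it. T and NK cell genes were lower in all 33 (median -1.12, adjusted p = 1.25e-07, and 0.557 with an estimated correlation). They also lost their call without LF 2 (0.0997, median -0.34). The pass without the B-cell-high libraries (0.0309, median -0.35) has the same limit. Without the epididymis-high ones (median -1.71) LF 2 was 1 of only 2 LF libraries, so that pass does not bear on LF 2 either. Neutrophil and mast cell genes were lower in 9 of 11 (median -0.54, adjusted p = 0.0083; adjusted p = 0.429 with an estimated correlation).

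Of the epididymis and testis list, the 5 measured members, all testis genes, were lower (median -4.56, adjusted p = 0.00807, and 0.557 with an estimated correlation). That call ended without LF 3 (0.0537) or LF 6 (0.0579), which had high levels of these genes. Genes biased to male liver, made by hepatocytes, were lower in 12 of 16 (median -1.44, adjusted p = 1.62e-05; adjusted p = 0.429 with an estimated correlation), and 9 fell when adjusted over the list alone. Their median was -0.93 without the B-cell-high libraries. The hepatocyte gene Alb stood at 136 CPM in LF 3, 172 in LF 5 and 208 in HF 5, against 11.9 to 55.8 in all other eWAT libraries. Over all genes edgeR passed 0 of 15987, with 1733 at an unadjusted p under 0.05 (604 higher and 1129 lower), DESeq2 69 (9 higher, 60 lower) and limma voom 0. Without LF 5 edgeR passed 13, all lower, among them Mcm5, Mcm6, Tk1, Cdt1, Pclaf and Marco. LF 5 had the lowest level in LF of each gene named here. Camera called 17 of 55 lists (4 higher, 13 lower), 10 without LF 2, 27 without HFLF 4 and 28 without the epididymis-high libraries, and 0 held with an estimated correlation or fry.

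**Figure D2:**
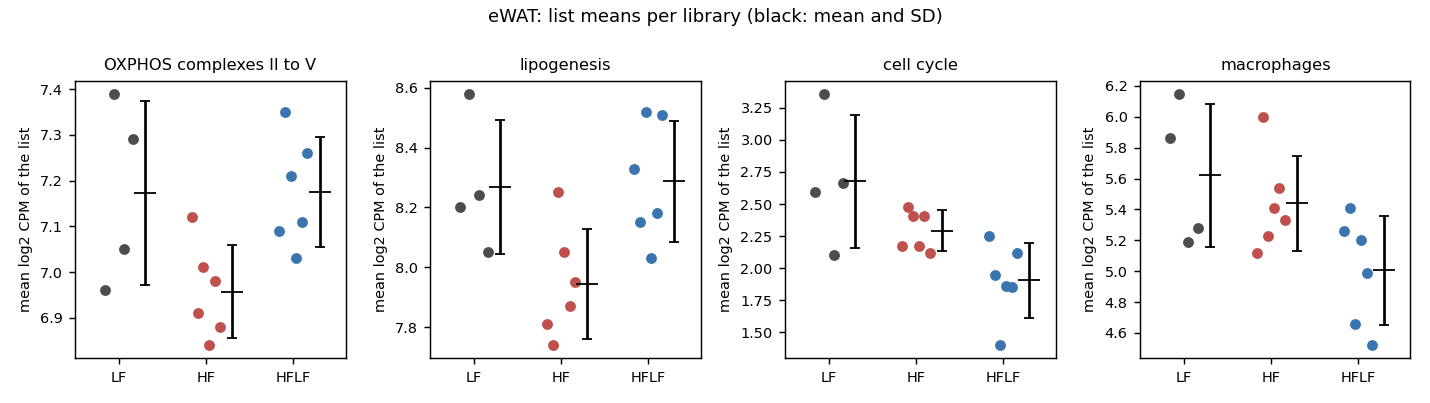
Mean log2 CPM of 4 gene lists in each eWAT library, with group means and SD. Cell cycle genes averaged 2.68 ± 0.52 in LF and 1.90 ± 0.29 in HFLF, and OXPHOS complexes II to V 6.96 ± 0.10 in HF and 7.17 ± 0.12 in HFLF.

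Most lists were called in eWAT between HFLF (n = 6) and HF (n = 6), where camera placed mitochondrial and fat-making genes higher and macrophage, interferon and B cell genes lower, but 0 lists held with an estimated correlation (smallest adjusted p = 0.295). T and NK cell genes did not pass (median -0.27, adjusted p = 0.236). Cycs, the electron carrier cytochrome c, stood at 52.3 ± 5.10 CPM in HFLF and 39.7 ± 2.65 in HF (0.40 ± 0.07, adjusted p = 0.245). The secreted phospholipase Pla2g2e stood at 9.55 ± 3.07 against 4.65 ± 0.884 (1.04 ± 0.20), and the folate enzyme Aldh1l1 differed by 0.58 ± 0.12. Lower in HFLF were the complement regulator Cfp (-0.52 ± 0.13) and the cytosolic phospholipase Pla2g4a (-0.53 ± 0.14). Irgc1, a testis GTPase, stood at 0.146 CPM in HFLF, near the floor, and 2.94 in HF, where HF 2 (6.74) and HF 6 (9.21), both epididymis-high, carried the mean. None passed over all genes.

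OXPHOS complexes II to V were higher in all 40 members (median 0.23, camera adjusted p = 5.39e-18; adjusted p = 0.295 with an estimated correlation), complex I in all 36 (0.20, 4.23e-16; adjusted p = 0.295 with an estimated correlation) and mitochondrial ribosome genes in 72 of 75 (0.13, 1.55e-14; adjusted p = 0.295 with an estimated correlation). TCA cycle genes were higher in all 19 (median 0.27, adjusted p = 9.85e-12; adjusted p = 0.295 with an estimated correlation), and fatty acid oxidation genes in 20 of 21 (0.24, 4.13e-11; adjusted p = 0.295 with an estimated correlation), of which 10 rose when adjusted over the list alone (0 over all genes). By the exact permutation test of list means the unadjusted p was 0.0108 for complexes II to V, 0.00649 for complex I and 0.00433 for the TCA cycle. After adjustment this test passed 0 of 55 lists (smallest adjusted p = 0.0893). The 5 camera calls held without any 1 library and without the B-cell-high or the epididymis-high libraries. The genes encoded by mitochondrial DNA were higher in all 8 (median 0.20, adjusted p = 0.0312; adjusted p = 0.535 with an estimated correlation), a call that ended without HF 2 (0.0945), HF 5 (0.0560), HFLF 1 (0.0973), HFLF 3 (0.0561), HFLF 5 (0.0529) or HFLF 6 (0.158), and without the B-cell-high (0.0882) or the epididymis-high libraries (0.113).

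Lipogenesis genes were higher in 24 of 28 members (median 0.38, adjusted p = 8.05e-08; adjusted p = 0.295 with an estimated correlation), with a mean log2 CPM of 8.29 ± 0.20 in HFLF and 7.95 ± 0.18 in HF. Genes of adipocyte identity were higher in 29 of 32 (median 0.18, adjusted p = 1.47e-06; adjusted p = 0.295 with an estimated correlation), and 5 rose when adjusted over the list alone, Agpat2, Dgat2, Slc2a4, Gpd1 and Rbp4. Cell cycle genes were lower in 35 of 37 (median -0.43, adjusted p = 2.7e-11) and macrophage genes in 32 of 35 (-0.46, 7.99e-10), each with an adjusted p = 0.295 with an estimated correlation. The macrophage median was -0.30 without HF 2 and -0.31 without the epididymis-high libraries. Interferon-induced genes were lower in 36 of 38 (median -0.29, adjusted p = 7.99e-10; adjusted p = 0.295 with an estimated correlation), with -0.17 without HF 5 and -0.19 without the B-cell-high libraries. B cell genes were lower in all 20 (median -2.14, adjusted p = 2.73e-06; adjusted p = 0.424 with an estimated correlation), with medians of -1.22 without HF 5 and -0.42 without the B-cell-high libraries. Mesothelium genes were lower in all 19 (-0.74, 5.46e-05; adjusted p = 0.436 with an estimated correlation), a call that ended without the B-cell-high libraries (0.0529). Of the single genes edgeR passed 0 of 15987, with 1486 at an unadjusted p under 0.05 (777 higher and 709 lower), DESeq2 52 (48 higher, 4 lower) and limma voom 0. Camera called 31 of 55 lists (17 higher, 14 lower), and 0 held with an estimated correlation or fry.

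**Figure D3:**
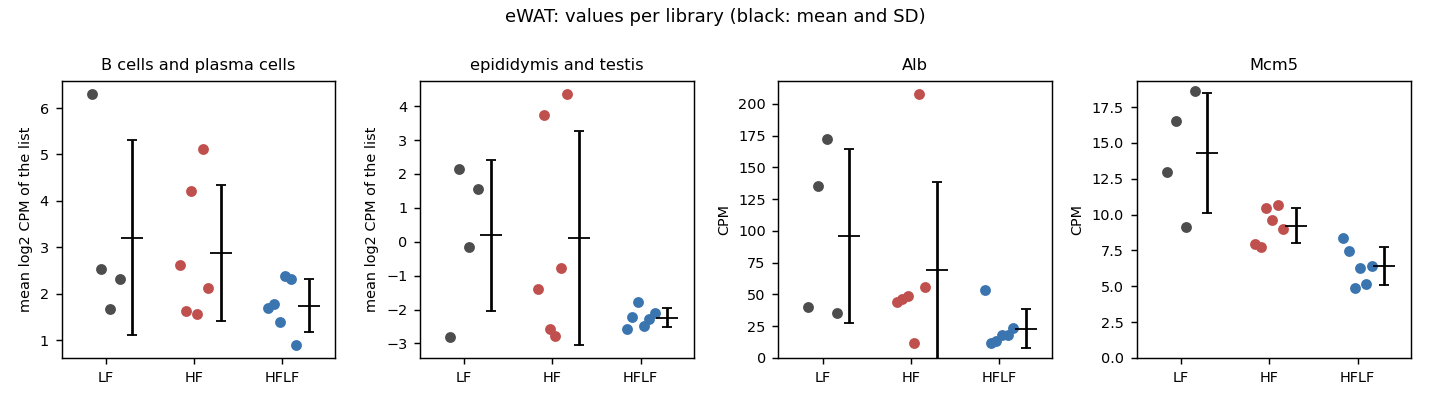
Markers of other tissues and of B cells in each eWAT library, with Mcm5. B cell genes stood at 6.31 in LF 2, and Alb at 208 CPM in HF 5.

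Targets of the microRNA let-7, named in the series title, did not pass as a list in any comparison. The listed targets Lin28a, Lin28b, Hmga2, Igf2bp1 and Trim71 were not measured in either tissue, so the result covers only the others. In liver the median over 42 targets was 0 in HF against LF (adjusted p = 0.767), -0.05 in HFLF against LF (0.346) and -0.02 in HFLF against HF (0.486). In eWAT the median over 45 targets was 0 (adjusted p = 0.858), -0.03 (0.419) and -0.08 (0.173). Dicer1, which cuts microRNA precursors, differed from LF by 0.05 ± 0.09 in HF liver, 0.15 ± 0.09 in HFLF liver, -0.02 ± 0.07 in HF eWAT and 0.05 ± 0.07 in HFLF eWAT.

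Whether an arm's change differed between liver and eWAT was tested over 12733 genes, and edgeR passed 0 for HF (621 at an unadjusted p under 0.05, smallest adjusted p 0.956) and 0 for HFLF (744, 0.415). DESeq2 was not run for this test, and limma voom passed 0 for each. The largest evidence was for Reep5, which differed by -0.74 ± 0.15 (-0.57 in liver and 0.17 in eWAT), and Nrp2, by 0.79 ± 0.18 (0.76 and -0.03), both in HFLF. For HF they were the peroxisome gene Pex16 (0.64 ± 0.16) and the microglial receptor P2ry12 (-1.62 ± 0.40).

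Changes of HF and HFLF against the same LF libraries correlated across genes at r = 0.709 in liver and 0.515 in eWAT. The LF libraries alone gave r = 0.575 (0.55 to 0.598) in liver and 0.614 (0.572 to 0.689) in eWAT in simulations of unchanged groups. By rank the values were 0.668 in liver (0.523 to 0.546 simulated) and 0.597 in eWAT (0.542 to 0.574). In eWAT the value lay below the simulated range by r and above it by rank. Genes were simulated without correlation between them, and labellings of the libraries spread far wider by rank (0.180 to 0.704 in liver, 0.201 to 0.771 in eWAT). Of 100 labellings, 6 gave as large a rank value in liver and 36 in eWAT, so no departure is shown by rank. The covariance was 0.0474 against 0.0378 simulated in liver (difference 0.00967), above the simulated range of 0.0351 to 0.0410, and 0.0780 against 0.0613 in eWAT (0.0167), inside its range of 0.0521 to 0.0785. Of 100 labellings 26 gave as large a covariance in liver and 47 in eWAT. At an unadjusted p under 0.05, 120 liver genes were higher in both arms and 108 lower, against 90.3 and 67.9 simulated and 7.4 and 6.1 for independent lists. In eWAT 151 were higher and 184 lower, against 122.7 and 85.3 simulated and 17 and 47.7 for independent lists. Of 100 labellings of the libraries, 30 gave as many liver genes higher in both and 34 as many lower, and 24 and 20 did in eWAT. With separate LF libraries for the 2 arms r was -0.046 to 0.206 in liver and -0.305 to 0.073 in eWAT.

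Positions on GRCm38 (GENCODE M21) of the leading genes were as follows. In liver, Nrp2 (ENSMUSG00000025969.15) lies on chromosome 1 at 62703285 to 62818695 and Gstp1 (ENSMUSG00000060803.6) on 19 at 4035407 to 4037985. In eWAT, Gapdh (ENSMUSG00000057666.18) lies on chromosome 6 at 125161715 to 125166467, Mcm5 (ENSMUSG00000005410.6) on 8 at 75109569 to 75128439, and Cycs (ENSMUSG00000063694.5) on 6 at 50562563 to 50566538.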

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

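The tests of explanations in this part were chosen after the results were seen. Of 594 groups of values tested for 1 library apart from the rest, 35 gave one, where 29.7 are due to chance at 1 in 20. Most are therefore chance flags, and those reported are given with the reason that it lay far from the others of its arm.

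In liver, LF 2 had the smallest total of its arm (9.2 M counts, others 15.2 to 15.7) and the fewest genes with a count of its arm (13665, others 13674 to 13675). HFLF 4 lay apart on the second principal component (-43.8, others 0.1 to 22.1), in mitochondrial stress genes (4.53, others 3.93 to 4.11) and in circadian genes (4.78, others 5.41 to 5.62). Other list means apart from their arm were lipoprotein genes in HFLF 2 (7.77), ER stress in LF 1 (7.04), B cells in HF 6 (2.24, others 0.77 to 1.14), exocrine pancreas in HFLF 5 (1.02), branched-chain catabolism in HF 3 (6.77) and DNA methylation in HF 6 (4.35). Single genes apart, in CPM, were Acta2 in LF 2 (3.37), Dicer1 in LF 2 (34.2), Fasn in LF 6 (174.9), G6pc in HF 6 (892), Gstp-ps in LF 6 (14.02), Lrp2 in HF 1 (0.571) and HFLF 1 (0.291), and Ppara in LF 1 (83.5).

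In eWAT, list means apart were PPAR-alpha targets in HFLF 2 (6.24), lipoprotein genes in HFLF 1 (5.43), male-biased liver genes in HFLF 1 (2.18), circadian genes in HF 2 (4.67), interferon genes in LF 6 (4.00), MHC class II in LF 2 (7.02), cholangiocytes in HFLF 6 (2.42), mesothelium in HFLF 6 (0.39, others 3.74 to 4.63), muscle in HFLF 4 (3.95) and hypoxia in LF 2 (5.89). Single genes apart, in CPM, were Fibin in LF 3 (3.39), Lrrc18 in HFLF 6 (0.0820, below the floor of 0.233 and so not a measured level), Mest in LF 3 (26.4, others 361 to 499), Pla2g4a in HF 1 (9.11) and Slc25a10 in HFLF 6 (497).

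Camera placed cell cycle and immune genes lower in HFLF than in LF eWAT, but 0 lists held with an estimated correlation (smallest adjusted p = 0.429), and the B and T cell calls ended without LF 2 (0.0961 and 0.0997). Lymph node tissue in LF 2 could explain the B cell genes: the difference in list means was -0.44 (SE 0.34) without the B-cell-high libraries against -1.47 ± 1.07 with them, and the 2 explanations cannot be told apart. For cell cycle genes the difference was -0.80 (SE 0.38) without those libraries against -0.77 ± 0.29, which argues against it. Testis tissue in some libraries could also explain cell cycle genes, at -0.44 (SE 0.27) without the epididymis-high libraries (6 against 2), and cannot be told apart. Since no epididymis gene of the list was measured, epididymis tissue as such was not tested. Macrophage genes gave -0.53 (SE 0.34) and -0.52 (SE 0.37) without either set against -0.62 ± 0.27, and cannot be told apart; an inherited change stays open and untested.

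The 76 OXPHOS subunits had a list mean higher by 0.21 ± 0.06 in HFLF than in HF eWAT, and the camera calls of their lists did not hold with an estimated correlation (adjusted p = 0.295). A bias of GC content and length could cause this, but corrected values gave 0.27 ± 0.06, which argues against it. Testis tissue in some libraries could also cause it, but the difference was 0.18 ± 0.07 without the epididymis-high libraries, which argues against it. A lower share of fat cells in HF, with all other cell types raised alike, would raise endothelial genes there as much as macrophage genes. Endothelial minus macrophage was 0.47 ± 0.17 (0.04 ± 0.08 and -0.43 ± 0.19), which argues against that form only. A share lowered by added macrophages need not raise endothelial genes, so the test cannot decide on it. Adipocyte identity differed by 0.20 ± 0.06, and a lower share of fat cells in HF stays open. An inherited change also stays open and untested.

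For genes at an adjusted p under 0.05 the real count was 0, which any grouping reaches (100 of 100), so regrouping the libraries tests nothing there. The highest others were 1, 22 and 102 in liver, 81, 284 and 4 in eWAT, and 2 and 11 between tissues. The grouping with 284 genes was the real one with LF 5 and HFLF 2 exchanged. At an unadjusted p under 0.05, 4 of 100 groupings gave as many genes as the real 1486 of eWAT HFLF against HF (highest other 1799), the only count of this kind below 5 of 100 among the 8 comparisons. For lists and correlations chance could not be excluded. For lists in liver, 23 of 100 gave as many as the real 16 (highest other 21), 17 as the real 19 (25) and 24 as the real 16 (25). In eWAT 23 gave as many as the real 19 (27), 45 as the real 17 (34) and 6 as the real 31 (32). The median of the other groupings was 12 lists in each liver comparison and 14, 16 and 15 in eWAT, so camera often called lists without a real grouping. For the correlation of fold changes, 5 of 100 were as high as 0.709 in liver (highest other 0.766) and 72 as high as 0.515 in eWAT (0.852).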

How the results depend on the processing

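All alternatives were planned except leaving out B-cell-high or epididymis-high libraries, the exact permutation test and leaving out libraries for correlations, which were chosen after the results were seen. The filter removed 0 genes, so the alternative without it was the same. The cause of the differences below was not tested.

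Gene counts were 0 by edgeR in all 6 comparisons. DESeq2 gave 1, 11 and 0 in liver (HF against LF, HFLF against LF, HFLF against HF) and 12, 69 and 52 in eWAT. Leaving out 1 library gave 0 to 0, except 0 to 13 for eWAT HFLF against LF. With the replicate number as a block, liver HFLF against LF gave 1 gene, Cpne2 (-0.69), chosen after its values were seen. Whether numbers pair the libraries of different arms was not tested. After removal of group means, those of the same number correlated at a mean of 0.11 over 13 pairs in liver and 0.08 over 14 in eWAT. Pairs of different numbers averaged -0.02 in each tissue.

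List counts by camera were 16, 19 and 16 in liver and 19, 17 and 31 in eWAT, and 0 in all 6 with estimated correlations and with fry. The exact permutation test also gave 0 in all 6, with its smallest adjusted p in eWAT HFLF against HF (0.0893). At these group sizes 1 list at small p alone could not pass it, but several together could. With 1 surrogate variable they were 9 (liver HFLF against LF), 10 (liver HFLF against HF) and 10 (eWAT HFLF against LF). Without epididymis-high libraries they were 7 (eWAT HF against LF) and 28 (eWAT HFLF against LF). Leaving out 1 library gave 11 to 18, 7 to 22 and 8 to 16 in liver and 17 to 24, 10 to 27 and 27 to 32 in eWAT.

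The correlation of fold changes was 0.771 in liver and 0.636 in eWAT for genes of at least 10 CPM, -0.046 to 0.206 and -0.305 to 0.073 with LF split, and 0.638 to 0.798 and 0.447 to 0.624 leaving out 1 library.

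Directions turned by more than 1 SE for the genes below. Genes close to 0 turned by less, such as liver Scd1 (0.06, and -0.25 without LF 6), G6pc (0.39, and -0.04 without HF 6) and Pck1 (-0.04, and 0.16 without LF 6) and eWAT Lep (0.29, and -0.01 without LF 3), all in HF against LF. In liver HFLF against LF, Fgf21 (0.51) was -0.83 with the replicate block and -0.92 without HFLF 4 (-0.92 to 1.39 leaving out 1 library). In eWAT HF against LF, without LF 3 Cd68 (-0.30) was 0.11 (-0.66 to 0.11 leaving out 1 library) and Ppargc1a (-0.21) 0.33 (-0.49 to 0.33), and Slc4a1 was 0.038 without LF 6 (-1.10 to 0.038). In eWAT HFLF against LF, Ppargc1a was 0.36 without LF 3 (-0.40 to 0.36), and with 1 surrogate variable Cxcl13 was 0.21, H2-DMb2 0.054 and H2-Ob 0.029.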

Other observations

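The tests of explanations in this part were chosen after the results were seen. In liver, red blood cell genes were lowest in HF (3.13 ± 0.34 mean log2 CPM, n = 5) and MHC class II genes, which mark antigen-presenting cells, were higher there than in LF in all 9 members (median 0.33, camera adjusted p = 0.0151; adjusted p = 0.587 with an estimated correlation). The call ended without LF 1 (0.174, median 0.18), HF 2 (0.0898, median 0.19) or HF 6 (0.163, median 0.07).

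In eWAT of the HFLF arm, histone genes, which package new DNA, were higher than in LF as a list (median 0.42, adjusted p = 0.000792, and 0.429 with an estimated correlation). Cell cycle genes were lower by camera (adjusted p = 0.429 with an estimated correlation), with a median of -0.43 without the epididymis-high libraries. The histone call ended without the epididymis-high libraries (adjusted p = 0.116), and the median was 0.15 without LF 3.

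Transcripts of hepatocytes appeared in some eWAT libraries. Over 61 genes high in liver, the excess in LF 3, LF 5 and HF 5 over the other eWAT libraries followed the liver levels at r = 0.88 (0.86 without Alb). The median share was 0.191, 0.226 and 0.325% of the liver level, from 0.109 to 1.15% per gene, and 60, 61 and 61 of the 61 genes stood above the median of the other libraries. The signal was graded, since 57 genes did so in HFLF 1, 56 in HF 3 and 52 each in HF 2 and HF 6, at median shares of 0.0384, 0.0291, 0.026 and 0.0269%. Hepatocyte RNA that reached these libraries could explain this, and the test fits it. Whether it came at dissection or in the laboratory was not tested.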
